A study of Homo sapiens with 6 samples.

How the data were processed

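RNA was measured in 6 libraries of the HCC38 breast cancer line, 3 controls and 3 with a CIP2A siRNA. Per the labels' protocols, siRNAs were delivered with Oligofectamine, poly(A) RNA was purified and libraries were made with a stranded TruSeq mRNA kit. One label describes the mock as transfection reagent alone, whereas the design text calls it a non-transfection control. Per the submitters' processing notes, bcl2fastq 2.17, STAR 2.5.4b, Subread 1.5.1 and the genome build hg38 were used. The annotation, the strand setting and the handling of reads that map to several genes are not given in the sources used here, so values of close paralogs and of overlapping or antisense genes are uncertain. The authors deposited whole-number read counts per gene, not normalized, in 1 table of 26485 genes with 1 column per library, per the file headers.

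Of the gene symbols, 51 had been changed to dates by a spreadsheet. The Entrez identifier in the same row restored 50 of these, 1 stayed unresolved, and 1016 genes had no Entrez identifier. KIAA1524 was renamed CIP2A, and other symbols are those of the table. Coordinates came from a RefSeq gene table of GRCh38.p14 and were found for 25919 genes. No mitochondrially encoded gene was listed. Chi-square per degree of freedom between the counts of libraries of 1 group lay between 3.22 and 18.1, so no library was a copy of another in its group, and pairs across groups were not compared in this way.

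Genes were filtered with filterByExpr (minimum count 10), which left 13562, and libraries were scaled with TMM. Tests used edgeR 4.0.16 (robust dispersions, glmQLFit and glmQLFTest) in R 4.3.3 with Benjamini-Hochberg adjusted p under 0.05. The model of the main comparison had the group as its only term and 4 residual degrees of freedom. Non-targeting siRNAs against mock came from a fit with 3 levels and 3 residual degrees of freedom. Each siRNA against the controls came from a fit with 4 levels, whose 2 residual degrees of freedom come from the controls alone. Log2 CPM values had a prior count of 2. DESeq2 1.42.0 and limma 3.58.1 were used beside edgeR.

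Before the data were examined, 30 gene lists were fixed: PP2A subunits, DNA replication, G2/M and mitosis, homologous recombination and checkpoint, other DNA repair, MYC targets, ribosomal proteins, p53 targets, interferon, NF-kB, MAPK-responsive genes, ATF4, ER chaperones, heat shock, cholesterol and fatty acid synthesis, glycolysis and hypoxia, oxidative phosphorylation, mitochondrially encoded genes, histones, apoptosis, autophagy, basal and luminal epithelium, epithelial junctions, mesenchymal and matrix genes, RNA interference, and markers of fibroblasts, leukocytes, endothelium, and adipocytes and melanocytes. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. With an estimated correlation, camera rests on the residual degrees of freedom given above (4, 3 or 2), which leaves it little power. A lack of calls there does not count against a list. Named genes were chosen by a rule fixed at the same time: CIP2A; up to 10 called genes per direction with mean log2 CPM of at least 1 and groups that do not overlap or, as none passed, the 10 with the smallest p; up to 4 list members with the smallest p; called genes of non-targeting siRNA against mock, of which there were none; and TOPBP1, MDC1, MYC and E2F1. Genes called with single siRNAs, between siRNAs, or by other tools were named after their values were seen.

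Alternatives planned in advance were RLE and upper quartile factors, DESeq2, limma-voom, no filter, a filter of CPM of at least 1 in 3 libraries, the replicate number as a block, the mock as a separate level, and each library left out in turn. Comparisons between siRNAs, camera per siRNA, and offsets for a quadratic in transcript GC content and log length were chosen after seeing the data. Transcript GC, length and 3' UTR sequences came from GENCODE 29, and GC and length were found for 96.9% of tested genes. The 3' UTR scan covered the 11388 genes with a UTR of at least 50 bases and a mean log2 CPM of at least 1. Each 7-mer present in at least 50 of these genes was scored by its association with the log2 ratio of a library to the controls, given UTR and transcript length and GC, beside 100 shuffles of the ratios over genes. The scan was repeated 20 times with the 7-mer picked in 1 random part of the genes and scored in the rest. The expected covariance of siRNAs that share controls came from 100 simulations of unchanged counts, with the spread estimated from all 3 controls. The overlap of their called genes was set beside that of the genes with the smallest p, at the same list sizes, in 50 simulations of unchanged counts with shared controls, a step chosen after seeing the data.

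Some steps were tested on simulated data: edgeR for the main comparison, non-targeting siRNA against mock and siCIP2A#1, the list test, and the 7-mer scan. The other comparisons, the other tools, the offsets, and the covariance and overlap steps were not. In counts drawn for the 13562 genes of the main comparison with 200 changed genes, edgeR recovered 62% of 1.5-fold, 94% of 2-fold, 100% of 4-fold and 100% of 8-fold changes, with 14 false calls among 192. For non-targeting siRNA against mock it recovered 12%, 78%, 96% and 100% of these sizes, and for siCIP2A#1 60%, 92%, 100% and 100%. Changes were planted only in genes above a minimum mean CPM, so recovery in genes of lower expression was not tested. In the main comparison each planted change was the same in all 3 siRNA libraries. The shares recovered there do not apply to changes that differ between siRNAs. The 7-mer scan, run on 11388 genes, found 20 of 20 planted 7-mers. These were drawn from common 7-mers only, so recovery of the rarer ones scored was not tested. Totals of 13995187 to 18161451 counts per library limit precision for genes near a count of 3.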

Results

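HCC38 is a human cell line from a ductal carcinoma of the breast that the labels class as triple negative and basal-like. CIP2A, also listed as KIAA1524, encodes an inhibitor of the phosphatase PP2A, and its protein also binds TOPBP1 in the DNA damage response. Reads from poly(A) RNA had been counted per gene in 6 libraries. The control group held 1 mock library and 1 library for each of 2 non-targeting siRNAs, SCR#2 and SCR#3. The silenced group held 1 library for each of 3 different CIP2A siRNAs, siCIP2A#1, siCIP2A#2 and siCIP2A#3. Nothing in the labels says that the libraries came from separate cultures, so p-values measure the spread between these libraries, which was not split into a biological and a technical part. The total count was 13995187 in the mock, 17116379 with SCR#2, 14743781 with SCR#3, 18161451 with siCIP2A#1, 15547526 with siCIP2A#2 and 16929828 with siCIP2A#3. A count of 3, taken as the floor, corresponded to 0.165 to 0.214 CPM (counts scaled to the library total) and covers counting error only, and 13562 genes had enough counts to be tested.

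The first question was how far each siRNA lowered its target. CIP2A lies on chromosome 3 from 108549864 to 108589438 in GRCh38. It stood at 98.9 CPM in the mock, 99.8 CPM with SCR#2 and 103 CPM with SCR#3. It stood at 16.3 CPM with siCIP2A#1, 45.8 CPM with siCIP2A#2 and 19.3 CPM with siCIP2A#3. The control mean was 101 ± 2.19 CPM and the silenced mean 27.1 ± 16.2 CPM (SD, n = 3 each), or 27.0% of control. With each siRNA fitted as its own level, CIP2A fell by 2.62 on the log2 scale with siCIP2A#1 (SE 0.13, edgeR adjusted p = 2.41e-04). It fell by 1.13 with siCIP2A#2 (SE 0.12, edgeR adjusted p = 0.0165) and by 2.38 with siCIP2A#3 (SE 0.13, edgeR adjusted p = 4.68e-04). With the 3 siRNAs as a group the log2 difference was -1.90 (SE 0.30), and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment did not call it (adjusted p = 0.708, range over the alternatives 1.20e-05 to 1.00). Without siCIP2A#2 the log2 difference was -2.50 and passed (edgeR adjusted p = 1.20e-05). It was -2.03 and also passed with the replicate number as a block (edgeR adjusted p = 0.0345), although these numbers do not pair the libraries. An exact two-sided permutation test over the 6 libraries gave p = 0.10, the smallest value that 3 against 3 can give.

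**Figure D1:**
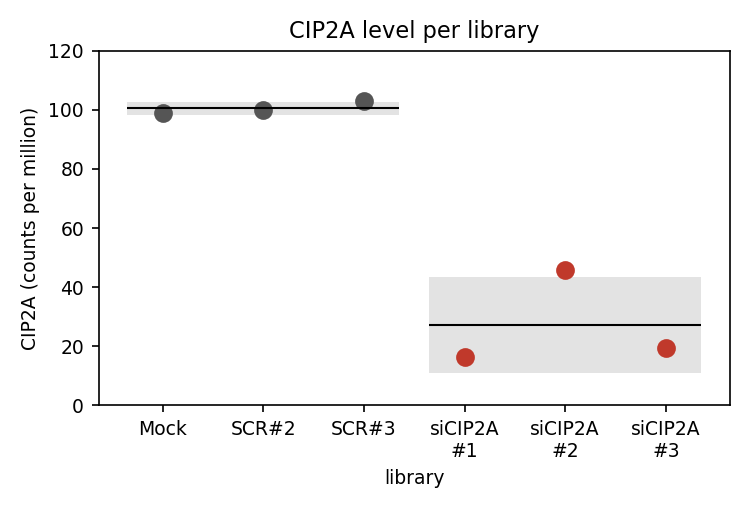
CIP2A in CPM, counts scaled to the library total (vertical axis), in each of the 6 libraries (horizontal axis; grey points controls, red points CIP2A siRNAs). Lines are group means and shaded bands 1 SD (n = 3 each); the 3 siRNA libraries lie at 16.3, 45.8 and 19.3 CPM, all below the controls at 98.9, 99.8 and 103 CPM.

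The main comparison asked which transcripts differed between the 3 CIP2A siRNAs as a group and the 3 controls. No transcript passed the test: 0 genes were called higher and 0 lower of 13562 by edgeR, with 369 genes at an unadjusted p under 0.05 where chance alone gives 678.1. DESeq2 called 3 genes. HMOX1, which encodes the inducible haem oxygenase, was higher by 0.69 (log2) and the neutral amino acid transporter gene SLC43A2 by 0.87, and the keratin-associated protein gene KRTAP2-3 was lower (log2 fold change -1.12), each with DESeq2 adjusted p = 0.0416. In edgeR the same genes had log2 differences of 0.69 (SE 0.15), 0.87 (SE 0.17) and -1.13 (SE 0.23), with adjusted p = 0.999 each, and edgeR with no filter called the same 3 genes. HMOX1 averaged 23.9 CPM in the controls and 38.4 CPM with the siRNAs, and SLC43A2 averaged 7.95 and 14.4 CPM (n = 3 each).

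Of the genes with a mean log2 CPM of at least 1 and groups that did not overlap, those with the smallest p did not pass edgeR's test either. On the higher side they included LAMA4, a laminin chain, at 0.58, LTBP1, which binds latent TGF-beta, at 0.41, and the arrestin-related gene ARRDC3 at 0.38 (log2). SCARF2 stood at 0.87, SLC16A6 at 1.26, ARID3A at 0.60, MYLK2 at 1.12 and GRAMD3 at 0.59. On the lower side were the complement gene C5 at -0.48, the WNT ligand gene WNT5B at -0.40 and the cyclin gene CCNA1 at -0.49. CCDC92 stood at -0.61, CDKN2AIPNL at -0.35, PM20D2 at -0.35, LRTOMT at -0.49, PQLC3 at -0.50 and IRGQ at -0.43. Groups did not overlap for 7.64% of the tested genes, 442 above and 594 below the controls, where chance gives 10%. TOPBP1 differed by -0.05 (SE 0.09), the damage scaffold gene MDC1 by -0.08 (SE 0.08), MYC by 0.05 (SE 0.13) and E2F1 by 0.04 (SE 0.11), and none passed. TOPBP1 lay between -0.12 (without siCIP2A#3) and 0.0061 (without siCIP2A#1), MYC between -0.11 (without siCIP2A#3) and 0.15 (without the mock) and E2F1 between -0.03 (without SCR#3) and 0.14 (without the mock), and MDC1 stood at -0.12 without siCIP2A#2. On simulated changes for this comparison, run on 13562 genes, edgeR recovered 62% of 1.5-fold and 94% of 2-fold changes. CIP2A was not among the 3 DESeq2 calls.

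Gene lists fixed before the data were examined were then compared. Camera with a preset correlation of 0.01 called 9 of 27 lists, 3 up and 6 down, and 0 with an estimated correlation. With an estimated correlation the test had 4 residual degrees of freedom and little power, so its 0 calls decide nothing. The preset 0.01 lay below the correlations estimated for most called lists. These were 0.70 for ATF4, 0.47 for cholesterol, 0.43 for replication, 0.35 for glycolysis, 0.35 for mitotic and 0.30 for mesenchymal genes. They were 0.15 for MAPK-responsive, 0.14 for recombination and -0.0011 for other repair genes. P-values at the preset may thus be far too small. Splits of the 6 libraries that mixed controls and siRNAs also called from 4 to 13 lists, so 9 calls do not set the real grouping apart. With 1 library left out the preset correlation called from 4 to 13 lists. Fry called 0 lists in 1 direction and 0 in its mixed test, and 0 members of any list passed over all genes tested or adjusted over the list alone. Targets of ATF4, the transcription factor of the amino acid response, rose as a list, with a median log2 difference of 0.27 and 25 of 26 members above 0 (camera adjusted p = 4.90e-08; adjusted p = 0.600 with an estimated correlation). SESN2, a stress-induced regulator of mTORC1, stood at 0.67, SLC3A2 at 0.44, STC2 at 0.41 and CHAC1 at 1.07. Glycolysis and hypoxia genes fell as a list, with a median of -0.15 and 23 of 27 members below 0 (camera adjusted p = 1.57e-06; adjusted p = 0.600 with an estimated correlation). PGK1 stood at -0.30, ENO2 at -0.30 and BNIP3 at -0.50, while the angiogenic factor gene VEGFA stood at 0.42. Without the mock, or with the mock as a separate level, the glycolysis list was not called (median -0.07 in each), and without siCIP2A#2 the ATF4 list was not called (median 0.01). Without siCIP2A#2 CHAC1 stood at 0.12, SESN2 at 0.25 and SLC3A2 at 0.18, and without the mock PGK1 stood at -0.17 and BNIP3 at -0.26.

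DNA replication genes fell as a list (median -0.11, 42 of 52 members below 0, camera adjusted p = 4.96e-06; adjusted p = 0.600 with an estimated correlation). Thymidylate synthase, TYMS, stood at -0.27, the origin licensing factor CDC6 at -0.29, POLA2 at -0.23 and MCM6 at -0.18. Mitotic genes (median -0.06, camera adjusted p = 0.00205; adjusted p = 0.720 with an estimated correlation) included the kinase gene AURKA at -0.19 and CCNB1 at -0.15. Homologous recombination and checkpoint genes (median -0.06, camera adjusted p = 0.00706; adjusted p = 0.600 with an estimated correlation) included FANCD2 at -0.21 and RAD51C at -0.17. Other DNA repair genes (median -0.04, camera adjusted p = 0.0486; adjusted p = 0.600 with an estimated correlation) included LIG3 at -0.27 and MSH6 at -0.14. Cholesterol and fatty acid synthesis genes (median -0.05, camera adjusted p = 0.0122; adjusted p = 0.740 with an estimated correlation) included CYP51A1 at -0.22 and FADS1 at -0.21. Calls ended for replication genes without the mock (median -0.07) or siCIP2A#2 (-0.06), for mitotic genes without siCIP2A#1 (-0.05) or siCIP2A#2 (-0.0031), and for recombination genes without siCIP2A#1 (-0.05) or siCIP2A#2 (-0.03). They ended for other repair genes without the mock (-0.05), SCR#3 (-0.04), siCIP2A#1 (-0.0042) or siCIP2A#2 (-0.03), and also with RLE or upper quartile factors, the replicate number as a block, the mock as a separate level, or GC and length offsets, so that 5 of 14 alternatives kept this call. They ended for cholesterol genes without SCR#3 (-0.04), siCIP2A#2 (-0.06) or siCIP2A#3, where the median turned to 0.02. The replication call also ended with the mock as a separate level, and FANCD2 stood at -0.12 without siCIP2A#2.

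Mesenchymal and matrix genes rose as a list (median 0.08, 23 of 33 members above 0, camera adjusted p = 0.0177; adjusted p = 0.720 with an estimated correlation). SMAD7, a feedback inhibitor of TGF-beta signalling, stood at 0.60, tenascin C, TNC, at 0.47 and fibronectin, FN1, at 0.25. MAPK-responsive genes rose as a list (median 0.07, camera adjusted p = 0.0364; adjusted p = 0.600 with an estimated correlation), with FOSB at 1.31, which stood at 0.61 without siCIP2A#3, and JUNB at 0.32. The mesenchymal call ended without the mock (median 0.06), SCR#3 (0.09) or siCIP2A#1 (0.0045), and with the mock as a separate level. The MAPK call ended without the mock (median 0.08), SCR#3 (0.06), siCIP2A#1 (0.07) or siCIP2A#3 (0.03), with the mock as a separate level, and with GC and length offsets (0.06), so that 8 of 14 alternatives kept it.

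The other 18 lists were not called. PP2A subunits and regulators had a median of -0.05 (camera adjusted p = 0.0655) with PPP2R3A at -0.27, and cytosolic ribosomal proteins -0.04 (camera adjusted p = 0.0655) with RPS4X at -0.15. Medians were -0.04 for oxidative phosphorylation (UQCRC2 at -0.29), 0.04 for NF-kB genes (ICAM1 at 0.28), 0.05 for apoptosis genes (BAK1 at 0.35) and 0.11 for epithelial junctions (ESRP1 at 0.49, CLDN1 at 0.21). They were 0.07 for basal epithelium, -0.10 for luminal epithelium (ERBB2 at 0.23), 0.02 for p53 targets (CCNG1 at -0.22) and -0.03 for MYC targets (ODC1 at 0.25). They were 0.03 for interferon genes (IFI27 at 0.67, ISG15 at 0.26), 0.02 for ER chaperones (HERPUD1 at 0.31), 0.03 for autophagy (BECN1 at -0.23) and -0.03 for heat shock genes (HSP90AA1 at -0.15). They were 0.02 for RNA interference genes (PRKRA at -0.42) and -0.10 for histones (HIST1H3H at 0.75), and the direction of the camera test was down for both RNA interference genes and histones, whose means were -0.01 and 0.03. Of markers of other cell types, leukocyte genes had a median of 0.11 and endothelial genes 0.02, with the camera direction of the endothelial genes down (mean -0.01). CD68, a macrophage marker that many tumour lines also express, reached 202 CPM and ROBO4 5.72 CPM, while PTPRC and CDH5 had 0 counts in every library. Fibroblast markers had 3 tested members, with COL1A1 at 0.79, PDGFRB at 0.40 and COL1A2 at -0.45, the adipocyte and melanocyte list had 1, PMEL at 0.21, and mitochondrially encoded genes had 0, so these lists were too small for the test.

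Some of these lists were called under alternatives. Ribosomal proteins were called in 7 of 14: with limma-voom, with no filter, with the strict filter, and without SCR#2, SCR#3, siCIP2A#2 or siCIP2A#3. Of 14 alternatives 3 called epithelial junctions (no filter, without SCR#3 or siCIP2A#3), 3 MYC targets (without SCR#2, SCR#3 or siCIP2A#3), 3 NF-kB genes (without the mock, SCR#3 or siCIP2A#2) and 3 oxidative phosphorylation (no filter, without SCR#2 or SCR#3). PP2A genes were called with no filter and without siCIP2A#3, interferon genes without SCR#3 and without siCIP2A#3, apoptosis and basal genes without SCR#3, and autophagy genes without siCIP2A#3. Single libraries also moved the medians: over left-out libraries they ranged from -0.00029 to 0.17 for NF-kB genes, 0.0049 to 0.08 for apoptosis genes, 0.03 to 0.24 for epithelial junctions, -0.01 to 0.06 for p53 targets and -0.0022 to 0.06 for ER chaperones. The ranges were -0.06 to -0.02 for oxidative phosphorylation, -0.07 to -0.03 for PP2A genes and 0.03 to 0.07 for basal epithelium. They moved members of these lists as well. Without siCIP2A#1 COL1A1 stood at 0.19, COL1A2 at -1.002, PDGFRB at -0.14, CLDN1 at 0.06 and UQCRC2 at -0.45. Without siCIP2A#2 UQCRC2 stood at -0.09, ISG15 at 0.09, HERPUD1 at 0.14, BECN1 at -0.15, ERBB2 at 0.11 and PMEL at 0.07. Without siCIP2A#3 ODC1 stood at 0.14, CLDN1 at 0.36 and HERPUD1 at 0.48, without the mock HIST1H3H at 1.29, and without SCR#2 ERBB2 at 0.15. COL1A2 stood at -0.15 and PDGFRB at 0.74 without siCIP2A#3, and PDGFRB at 0.82 without SCR#2 and 0.19 without SCR#3.

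The design also allowed each siRNA to be compared with the 3 controls. Each siRNA had 1 library, assumed to vary like the controls, so the calls are differences of that library. With siCIP2A#1, 8 genes rose and 8 fell by edgeR. The calcium-binding protein gene CALB2 rose by 1.90 (SE 0.17), the matrix genes SPARC by 1.25 (SE 0.13) and COL1A1 by 1.52 (SE 0.17), the adhesion gene MCAM by 1.53 and the apolipoprotein gene APOE by 1.33. SEMA7A rose by 1.29, TMC8 by 1.43 and the glucose transporter gene SLC2A3 by 0.85. Besides CIP2A, the RNA-binding protein gene GRSF1 fell by 0.96, MEX3C fell by 1.01, LMLN fell by 1.69, CDV3 fell by 0.70, TMX2 fell by 0.89, TOMM5 fell by 0.77 and the lysosomal gene PSAP fell by 0.67. The edgeR adjusted p of these 16 genes lay between 2.41e-04 and 0.0493. With RLE factors CDV3, SLC2A3, TMX2, TOMM5 and PSAP were not called, with the strict filter PSAP was not, and with DESeq2 TMC8 was not.

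With siCIP2A#2, 7 genes rose and 3 fell. The risers were CHAC1, a glutathione-degrading enzyme, at 2.06 (SE 0.20), SESN2 at 1.28 (SE 0.13), TRIB3 at 1.00, DDIT3 at 0.96 and the serine synthesis gene PSAT1 at 0.88, all 5 of them members of the ATF4 list, and GUCA1B at 1.83 and LOC729603 at 1.90. Besides CIP2A, SCML1 fell by 1.53 (SE 0.16) and the ER oxidase gene ERO1A fell by 0.94 (SE 0.11). The edgeR adjusted p of these 10 genes lay between 0.0165 and 0.0332. With siCIP2A#3 only CIP2A was called by edgeR, 0 higher and 1 lower, with 1115 genes at an unadjusted p under 0.05. DESeq2 called 22 higher and 53 lower genes with siCIP2A#1, 38 and 23 with siCIP2A#2, and 5 and 24 with siCIP2A#3.

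CIP2A was the only gene shared by the edgeR calls of any pair of siRNAs, where lists of 16, 10 and 1 genes are too short to show whether other effects were shared. The covariance of log2 changes across genes was 0.0183 for siCIP2A#1 and siCIP2A#2, against 0.0132 simulated for unchanged groups with the same controls. It was 0.00101 for siCIP2A#1 and siCIP2A#3 against 0.0133, and 0.00434 for siCIP2A#2 and siCIP2A#3 against 0.0132. Correlations across genes were 0.229, 0.0132 and 0.0536, against 0.260, 0.266 and 0.255 simulated, and genes are not independent replicates. The mean excess covariance was -0.00537 with an SD over the 3 pairs of 0.00918, and 0.00193 without the mock, where its sign turned. The excess without the mock was 0.0133 for siCIP2A#1 and siCIP2A#2, -0.00830 for siCIP2A#1 and siCIP2A#3, and 7.64e-04 for siCIP2A#2 and siCIP2A#3. The simulations took their spread from all 3 controls in every setting. SCR#2 and SCR#3 lay closer together, with a median SD of log2 CPM of 0.066 against 0.12 for the 3 controls. The median SD of 2 values tends to lie below that of 3, which makes part of this gap. Chi-square per degree of freedom between counts was 3.22 for SCR#2 and SCR#3, and 11.4 and 9.06 for the mock with each. The covariance expected without the mock may thus be too high, and the sign of the mean excess there decides nothing. The number of calls rested on the controls used: without the mock edgeR called 1896 genes with siCIP2A#1, 3088 with siCIP2A#2 and 1330 with siCIP2A#3, without SCR#2 102, 40 and 33, and without SCR#3 85, 50 and 32. Each siRNA had 1 library, which was assumed to vary like the controls in the fit. With 1 control left out, the others gave all of the spread, with 1 residual degree of freedom. The counts without the mock thus rest on the difference between SCR#2 and SCR#3 alone.

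List medians are given for each siRNA, and their differences between siRNAs were not tested. With an estimated correlation camera had 2 residual degrees of freedom per siRNA and little power, so its lack of calls decides nothing. The ATF4 list rose with siCIP2A#2, with a median of 0.60, 5 members called over all genes and 23 of 26 adjusted over the list alone (camera adjusted p = 2.81e-52; adjusted p = 0.351 with an estimated correlation). Its median was -4.30e-04 with siCIP2A#1 and -0.01 with siCIP2A#3, with 0 members called in either. The mesenchymal list rose with siCIP2A#1 (median 0.30, 12 of 33 members adjusted over the list alone, camera adjusted p = 3.61e-12; adjusted p = 0.516 with an estimated correlation), and was called lower with siCIP2A#3 (median -0.09, 7 of 33 members adjusted over the list alone, camera adjusted p = 0.00564; adjusted p = 0.706 with an estimated correlation). Marker lists of other cell types moved the same way without being called as lists: endothelial medians were 0.29 with siCIP2A#1 and -0.42 with siCIP2A#3, and leukocyte medians 0.54 and -0.05. Of the fibroblast markers, COL1A1 stood at 1.52 with siCIP2A#1 and -0.04 with siCIP2A#3, PDGFRB at 1.06 and -0.68, and COL1A2 at 0.21 and -1.32. PDGFRB and COL1A2 averaged only 1.11 and 0.76 CPM in the controls. Cholesterol genes fell with siCIP2A#3 (median -0.28, 10 of 32 members adjusted over the list alone, camera adjusted p = 1.96e-14; adjusted p = 0.706 with an estimated correlation), and with siCIP2A#2 (median -0.11, camera adjusted p = 0.0405; adjusted p = 0.699 with an estimated correlation), and were called higher with siCIP2A#1 (median 0.10, camera adjusted p = 9.06e-04; adjusted p = 0.516 with an estimated correlation). Replication genes were called lower with siCIP2A#1 (median -0.15, camera adjusted p = 3.13e-05; adjusted p = 0.543 with an estimated correlation) and siCIP2A#2 (median -0.17, camera adjusted p = 2.76e-08; adjusted p = 0.671 with an estimated correlation) and not with siCIP2A#3 (median 0.03). Mitotic genes were called lower with siCIP2A#1 (median -0.10, camera adjusted p = 0.00218; adjusted p = 0.516 with an estimated correlation) and siCIP2A#2 (median -0.19, camera adjusted p = 5.19e-07; adjusted p = 0.671 with an estimated correlation), and higher with siCIP2A#3 (median 0.05, 37 of 50 members above 0, camera adjusted p = 0.0321; adjusted p = 0.807 with an estimated correlation). Recombination genes were called lower with siCIP2A#1 (median -0.08, camera adjusted p = 0.00794; adjusted p = 0.516 with an estimated correlation) and siCIP2A#2 (median -0.17, camera adjusted p = 5.51e-04; adjusted p = 0.671 with an estimated correlation) and not with siCIP2A#3 (median 0.03). MAPK-responsive genes were called higher with siCIP2A#3 alone (median 0.16, 21 of 26 members above 0, 4 adjusted over the list alone, camera adjusted p = 1.82e-08; adjusted p = 0.706 with an estimated correlation), with medians of 0.09 with siCIP2A#1 and -0.10 with siCIP2A#2. Glycolysis genes were called lower with siCIP2A#2 alone (median -0.22, camera adjusted p = 1.11e-04; adjusted p = 0.699 with an estimated correlation), with medians of -0.12 with siCIP2A#1 and -0.13 with siCIP2A#3. Other repair genes were called with no siRNA (medians -0.06, -0.05 and -0.01). With GC content and length removed from the log2 ratios, the cholesterol median was 0.06 with siCIP2A#1, -0.14 with siCIP2A#2 and -0.25 with siCIP2A#3. Camera called 11 lists with siCIP2A#1, 9 with siCIP2A#2 and 6 with siCIP2A#3, and 0 with an estimated correlation in each.

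**Figure D2:**
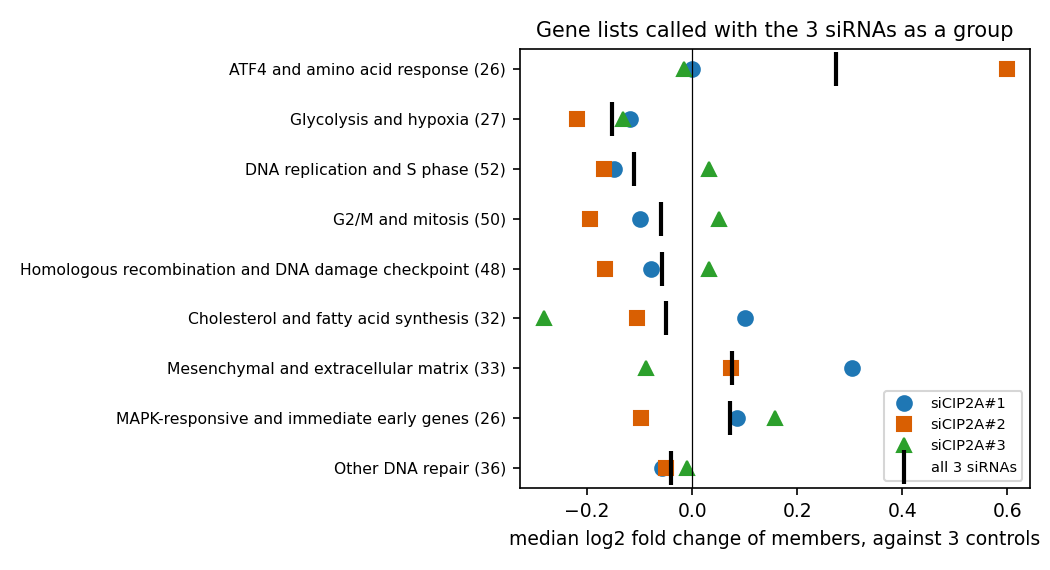
Median log2 fold change of list members against the 3 controls (horizontal axis) for the 9 lists called with the 3 siRNAs as a group (vertical axis, tested members in parentheses); circles, squares and triangles are siCIP2A#1, siCIP2A#2 and siCIP2A#3, each 1 library, and bars the 3 siRNAs together. The ATF4 list lies at 0.60 with siCIP2A#2 and near 0 with the others, and the cholesterol list at -0.28 with siCIP2A#3 and 0.10 with siCIP2A#1.

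Direct comparisons of siRNAs were chosen after seeing the data, and their genes were named after their values were seen. Each siRNA had 1 library and the spread came from the 3 controls alone, so variation between cultures with the same siRNA was not measured, and the calls are differences between libraries. With 1 control left out, the spread came from the other controls, with 1 residual degree of freedom. Between the libraries of siCIP2A#1 and siCIP2A#3 edgeR called 49 genes higher and 20 lower with siCIP2A#1. Of 33 mesenchymal and matrix genes 5 were higher: SPARC by 1.90, ANKRD1 by 2.18, TGFBI by 0.83, TGFB2 by 1.57 and CYR61 by 0.82. Of 32 cholesterol and fatty acid genes 3 were higher, the SREBP regulator INSIG1 by 1.36, HMGCS1 by 0.95 and fatty acid synthase, FASN, by 1.00. TMC8 was higher by 3.00, and MEX3C (-1.27), TMX2 (-1.14) and LMLN (-1.80) were lower. Between the libraries of siCIP2A#1 and siCIP2A#2 edgeR called 0 genes higher and 2 lower, PSAP (-1.16) and CIP2A (-1.49), each with edgeR adjusted p = 0.0302. Between those of siCIP2A#2 and siCIP2A#3 edgeR called 0 genes, with 2116 at an unadjusted p under 0.05 and 57 higher and 39 lower by DESeq2. Without the mock these 3 comparisons gave 2302 (siCIP2A#1 and siCIP2A#2), 2477 (siCIP2A#1 and siCIP2A#3) and 3026 genes, without SCR#2 113, 241 and 138, and without SCR#3 101, 213 and 108.

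The 7-mers of 3' UTRs were scored against the ratio of each library to the controls, also after seeing the data. The 7-mer with the lowest score was AACCACA with siCIP2A#1 (-18.3, mean shift -0.12 on the log2 scale), AAGGCAT with siCIP2A#2 (-8.77, shift -0.06) and GAATCAG with siCIP2A#3 (-9.97, shift -0.07). Genes with these 7-mers were 1577, 1499 and 1399 of 11388. When the 7-mer was picked in a random set of genes and scored in the remaining genes, over 20 draws, the median score was -12.9, -6.30 and -6.78 for the siRNAs and -0.313, -0.673 and -0.593 for the mock, SCR#2 and SCR#3.

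**Figure D3:**
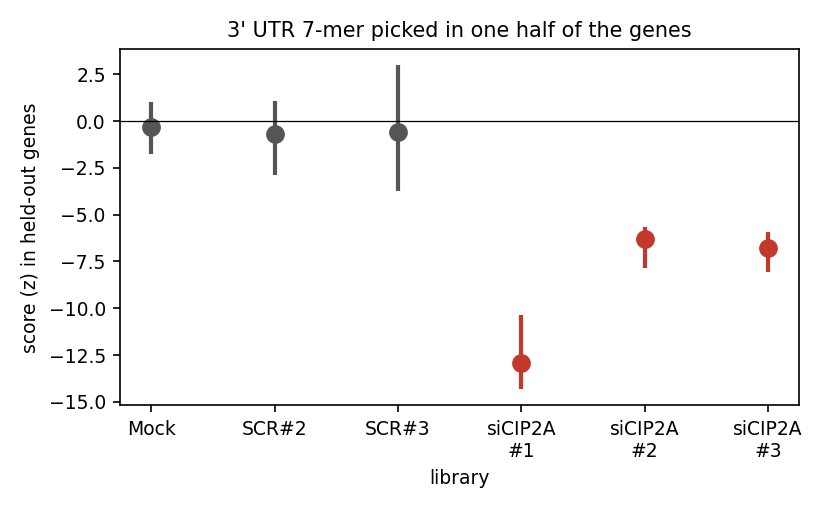
Score (z, vertical axis) of the most negative 3' UTR 7-mer, picked in a random set of genes and scored in the genes left out, for each library (horizontal axis; grey controls, red CIP2A siRNAs). Points are medians and bars the lowest and highest of 20 draws; the siRNA medians lie at -12.9, -6.30 and -6.78 and the control medians at -0.313, -0.673 and -0.593.

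The controls were compared to see how transfection with a non-targeting siRNA differed from mock. No gene was called by edgeR, 0 higher and 0 lower, with 856 at an unadjusted p under 0.05. DESeq2 called 3 genes lower with the non-targeting siRNAs, named after their values were seen, and edgeR with no filter called these 3 and also SIVA1 (-0.82) and C9orf16 (-0.95) lower. The gene MBD3 was lower (log2 fold change -0.82, DESeq2 adjusted p = 0.00449), the cytokine gene MIF too (-0.88, DESeq2 adjusted p = 0.0274) and the ribosome biogenesis gene BOP1 (-0.83, DESeq2 adjusted p = 0.0274). MBD3 stood at 115 CPM in the mock, 65.3 CPM with SCR#2 and 64.5 CPM with SCR#3. It lay between these with siCIP2A#1, siCIP2A#2 and siCIP2A#3, at 92.1, 93.5 and 95.4 CPM. IFI44, an interferon-induced gene, stood at 4.15 CPM in the mock, 9.47 CPM with SCR#2 and 9.09 CPM with SCR#3, and was not called (edgeR adjusted p = 0.610). With siCIP2A#1, siCIP2A#2 and siCIP2A#3 it stood nearer the non-targeting libraries, at 8.06, 9.24 and 8.19 CPM. Camera called 6 of 27 lists, 1 up and 5 down, and 0 with an estimated correlation. Interferon genes rose (median 0.22, camera adjusted p = 1.00e-04; adjusted p = 0.976 with an estimated correlation), and glycolysis genes (median -0.34, camera adjusted p = 1.71e-09; adjusted p = 0.461 with an estimated correlation) and MYC targets (median -0.19, camera adjusted p = 1.16e-07; adjusted p = 0.976 with an estimated correlation) fell. Replication genes (median -0.12, camera adjusted p = 3.08e-04), ribosomal proteins (median -0.07, camera adjusted p = 7.93e-04) and histones (median -0.28, camera adjusted p = 0.00868) fell too, with adjusted p = 0.976, 0.976 and 0.703 with an estimated correlation. The ratio moved with transcript GC content: its median was 0.18 in the lowest GC decile of genes and -0.34 in the highest. With GC content and length removed from the log2 ratios, the list median was -0.16 for histones (-0.29 before), -0.26 for glycolysis genes, -0.17 for MYC targets, -0.13 for replication genes, -0.05 for ribosomal proteins and 0.20 for interferon genes. The ratio of SCR#2 to SCR#3 had medians of 0.01 and -0.01 in the same deciles. The mock is 1 library, assumed to vary like the other libraries. Camera with an estimated correlation had 3 residual degrees of freedom here and little power, so its lack of calls decides nothing.

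**Figure D4:**
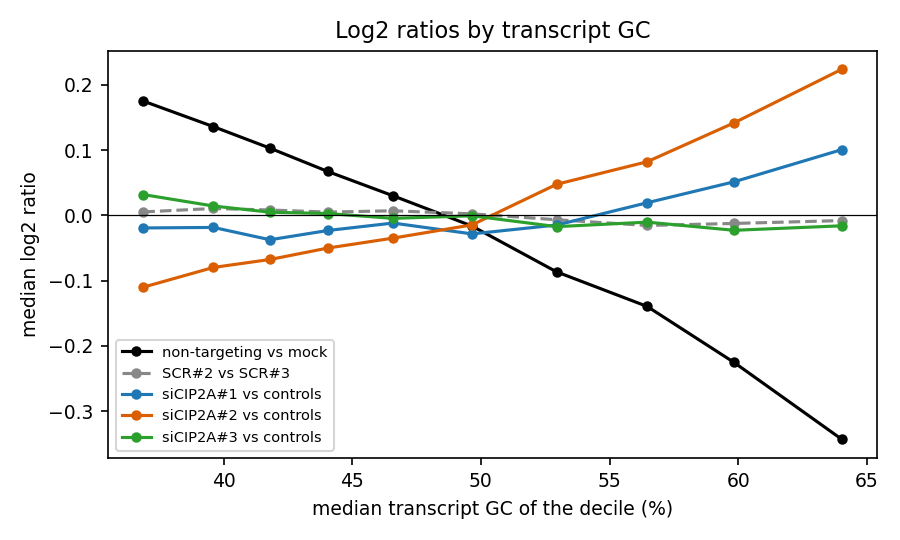
Median log2 ratio (vertical axis) of genes grouped into deciles of transcript GC content (horizontal axis, median GC of each decile in percent). Black is non-targeting siRNAs over mock, dashed grey SCR#2 over SCR#3, and colours each CIP2A siRNA over the 3 controls; the black line runs from 0.18 to -0.34 and the siCIP2A#2 line from -0.11 to 0.22.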

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

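The score of 7-mers against shuffles and the comparison of ATF4 medians between siRNAs were chosen after the results were seen, and the contrasts between siRNAs were not planned. Groups of 3 libraries were not searched for single outlying values.

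Libraries of different siRNAs were compared with each other, with 1 library each and the spread taken from the 3 controls, so that variation between cultures with the same siRNA was not measured. Fits with 1 control left out had 1 residual degree of freedom. edgeR called 69 genes between the siCIP2A#1 and siCIP2A#3 libraries (213 to 2477 with 1 control left out) and 2 between those of siCIP2A#1 and siCIP2A#2 (101 to 2302). Of these 2, 1 was CIP2A itself, by -1.49 on the log2 scale.

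The edgeR calls of the siRNAs had only CIP2A in common, in lists too short to show a lack of sharing. Unequal loss of CIP2A would give the highest excess covariance to siCIP2A#1 and siCIP2A#3, the pair with the deepest loss. The excess of this pair was -0.0123, below the 0.00504 of siCIP2A#1 with siCIP2A#2, also with each control left out in turn. It was also below the -0.00886 of siCIP2A#2 with siCIP2A#3, from which it hardly differed without SCR#2 (-0.0139 each). These covariances were not corrected for GC content, with which siCIP2A#1 and siCIP2A#2 rose (Spearman correlation 0.146 and 0.402) and siCIP2A#3 did not (-0.0677). The order of pairs argues against unequal loss as the whole reason only if GC trends did not set it, which was not tested. GC content and length explained 3.35%, 13.1% and 0.884% of the variance of siCIP2A#1, siCIP2A#2 and siCIP2A#3 and cannot be told apart from other causes for part of siCIP2A#2. Seed matches of the siRNA strands in 3' UTRs are a candidate explanation for lowered genes: the lowest 7-mer scores of -18.3, -8.77 and -9.97 passed the lowest shuffles at -5.92, -4.83 and -5.08, while SCR#2 (-4.89 against -4.79) and SCR#3 (-5.37 against -4.80) passed narrowly and the mock (-3.79 against -4.89) did not. With the 7-mer picked and scored in separate genes the median score was -12.9, -6.30 and -6.78 for the siRNAs and -0.313, -0.673 and -0.593 for the controls. Among the 100 genes most lowered the share with the 7-mer was 3.97, 2.66 and 1.38 times that of all genes, which decides nothing because 7-mers picked in the same way for controls reached 3.82, and effects of CIP2A loss that differ between libraries stay open.

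The mock stood apart from SCR#2 and SCR#3. GC content and length explained 31.5% of the variance of the ratio of non-targeting siRNA to mock and 0.212% of that of SCR#2 to SCR#3. The mock and the non-targeting libraries thus differed with GC content, and which side departed was not settled. Against the 3 controls siCIP2A#2 also stood higher in the highest GC decile (0.22) than in the lowest (-0.11), as the mock did against the non-targeting libraries. For siCIP2A#1 these medians were 0.10 and -0.02, and for siCIP2A#3 -0.02 and 0.03. An interferon response to double-stranded RNA cannot be told apart from other differences: the interferon median was 0.22, but the endothelial list stood higher at 0.45. As the mock is 1 library, a difference of reagent and a difference of library preparation stay open.

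The ATF4 list stood high with siCIP2A#2 and not with the other siRNAs, a difference between siRNAs that was not tested for the list. Loss of CIP2A as its cause is argued against, since the higher of the medians with siCIP2A#1 and siCIP2A#3, which lowered CIP2A further, was -4.30e-04, against 0.60 with siCIP2A#2. GC content is argued against as the whole cause, since 85.9% of the median was kept after the correction. Another effect of this siRNA, or of its single culture or library, was not tested and stays open.

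For genes called with the 3 siRNAs as a group the real count was 0, so that all 10 splits of the 6 libraries gave at least as many by construction, and the highest other split gave 2. For lists, 4 of 10 splits gave at least the real 9, and the highest other gave 13. With 10 splits no share under 0.05 is possible.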

How the results depend on the processing

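Contrasts between siRNAs, lists per siRNA and GC and length offsets were chosen after seeing the data. Of 1782 values of named genes and lists under alternatives, 1666 kept their direction and side of the threshold, 40 gained a call, 36 lost one and 40 reversed, and the cause was not tested for any change below. With the 3 siRNAs as a group, DESeq2 called 2 genes higher and 1 lower, as did edgeR with no filter. The replicate number as a block, whose numbers do not pair the libraries, gave 1 gene lower, CIP2A at -2.03, and histones at -0.089. With the mock as a separate level 4 lists were called, and ribosomal proteins stood at -0.0092 and heat shock genes at -0.0062 (with reversed test directions), luminal genes at 0.0039, MYC targets at 0.043, histones at 0.11 and interferon genes at -0.041. With GC and length offsets E2F1 stood at -0.028, heat shock genes at 0.0043 and histones at -0.049. Non-targeting siRNA against mock gave 3 genes with DESeq2 and 5 with no filter. For siCIP2A#1, siCIP2A#2 and siCIP2A#3 against the controls DESeq2 called 75, 61 and 29 genes, no filter 169, 109 and 44, and GC and length offsets 509, 255 and 170. Between siCIP2A#1 and siCIP2A#2, siCIP2A#1 and siCIP2A#3, and siCIP2A#2 and siCIP2A#3, DESeq2 called 89, 144 and 96 genes and GC and length offsets 648, 1096 and 770. Over left-out libraries CIP2A ranged from -2.50 to -1.63, genes called lower from 0 to 1 and lists called from 4 (without siCIP2A#1) to 13 (without SCR#3 or siCIP2A#3). Genes called ranged from 85 to 1896 with siCIP2A#1, 40 to 3088 with siCIP2A#2 and 32 to 1330 with siCIP2A#3, and from 101 to 2302, 213 to 2477 and 108 to 3026 between the siRNAs in the order above, the highest without the mock each time. TOPBP1 ranged from -0.12 to 0.0061, MYC from -0.11 to 0.15, E2F1 from -0.033 to 0.14, CD68 from -0.16 to 0.0071 and PDGFRB from -0.14 to 0.82. Medians ranged from -0.014 to 0.062 for autophagy, -0.17 to 0.016 for cholesterol, -0.072 to 0.0094 for ribosomal proteins, -0.23 to 0.22 for endothelial, -0.063 to 0.041 for heat shock, -0.17 to 0.31 for leukocyte and -0.21 to 0.042 for luminal genes. They ranged from 0.032 to 0.11 for MAPK, 0.0045 to 0.17 for mesenchymal, -0.11 to 0.043 for MYC target, -0.17 to 0.11 for histone, -0.073 to 0.030 for RNA interference and -0.039 to 0.13 for interferon genes, and a list counted as reversed by the direction of its test, not of its median. The mean excess covariance of the siRNAs was -0.00910 without SCR#2, -0.00805 without SCR#3 and -0.00497 in genes with mean log2 CPM of at least 1, and its sign turned without the mock, at 0.00193, a move within the SD over the 3 pairs of 0.00918. The simulated spread stayed that of all 3 controls when 1 was left out, so this turn of sign decides nothing. Without 1 library 25 of 72 named genes of the main comparison moved by over 1.5 times. Depth limits genes near 3 counts.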

Other observations

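Tests of lists per siRNA, GC offsets and 7-mers were chosen after seeing the data. The median of interferon genes was 0.20 with siCIP2A#2 (29 of 38 members above 0, camera adjusted p = 0.00136; adjusted p = 0.699 with an estimated correlation), 0.10 with siCIP2A#1 and -0.14 with siCIP2A#3. Epithelial junction genes had medians of 0.25 with siCIP2A#1 (camera adjusted p = 0.00180; adjusted p = 0.516 with an estimated correlation), 0.23 with siCIP2A#2 and -0.24 with siCIP2A#3. Luminal genes stood at -0.32 with siCIP2A#3 (camera adjusted p = 0.00762; adjusted p = 0.706 with an estimated correlation), autophagy and lysosome genes at 0.15 with siCIP2A#2 (camera adjusted p = 5.51e-04; adjusted p = 0.671 with an estimated correlation) and MYC targets at 0.10 with siCIP2A#3 (camera adjusted p = 0.00191; adjusted p = 0.807 with an estimated correlation). MYC targets were called in the other direction with siCIP2A#1 (median -0.10, camera adjusted p = 0.00231; adjusted p = 0.691 with an estimated correlation) and siCIP2A#2 (median -0.09, camera adjusted p = 0.0318; adjusted p = 0.924 with an estimated correlation). None of these calls held with an estimated correlation, a test with 2 residual degrees of freedom per siRNA and too little power to decide. Differences between siRNAs were not tested for these lists.

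Called genes went with the 7-mers as follows. Of the genes called lower with siCIP2A#1 and scanned, CIP2A aside, 6 of 7 had AACCACA in the 3' UTR (GRSF1, LMLN, CDV3, TMX2, TOMM5 and PSAP, not MEX3C), as did 0 of 8 called higher. Both genes called lower with siCIP2A#2, SCML1 and ERO1A, had AAGGCAT, as did 0 of 6 called higher. The 7-mers had been picked on the same ratios. The 7-mer itself was found in the CIP2A transcript (4075 bases) for siCIP2A#3 but not for siCIP2A#1 or siCIP2A#2, whose transcript match was the reverse complement alone. The reverse complement was also found for siCIP2A#3 and for SCR#3. Of the 16199 scored 7-mers 32.3% occurred on either strand of this transcript, which gives a chance of 0.0337 that 3 random 7-mers all match on either strand. That value treats all scored 7-mers alike, whereas the picked ones were common, in 12.3% to 13.8% of scanned genes. It is therefore no test of these matches. The siRNA sequences were not used here, so the strand that each 7-mer would pair with was not settled.

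Without the mock, all 3 siRNAs called 75 genes higher and 18 lower in common. Independent lists of these sizes would share 6.02 and 4.31, but the comparisons share their controls, and in 50 simulations of unchanged counts with 2 shared controls the genes with the smallest p, in lists of these sizes, shared 72.8 (46 to 92) and 51.1 (32 to 66). The overlap of higher genes lay within the simulated range and that of lower genes below it. The simulated lists held only genes moved by noise, much of it from the shared controls, which raises their overlap. An overlap within or below the range therefore does not argue against a shared effect, and CIP2A itself was among the lower genes. Without the mock the fits had 1 residual degree of freedom, from SCR#2 and SCR#3 alone. Of the pairs, siCIP2A#1 and siCIP2A#2 shared 442 higher genes, above the 308 (271 to 352) simulated, while siCIP2A#1 and siCIP2A#3 shared 64 lower genes, below the 123 (104 to 144) simulated, and siCIP2A#2 and siCIP2A#3 shared 126, below 178 (158 to 200). The other pairs lay within the simulated range: 236 lower genes of siCIP2A#1 and siCIP2A#2 (223, 200 to 251), 134 higher of siCIP2A#1 and siCIP2A#3 (158, 134 to 181) and 224 higher of siCIP2A#2 and siCIP2A#3 (215, 194 to 237). HMOX1, SLC43A2, SMAD7, VEGFA and ARRDC3 were among the 75 genes and CIP2A, KRTAP2-3, C5, WNT5B and PM20D2 among the 18. The 75 also held MBD3, MIF and SIVA1, which stood lower with both non-targeting siRNAs than in the mock. The median transcript GC content was 62.5% for the 75 genes and 40.0% for the 18, against 48.0% for all tested genes. The simulated counts held no GC trend. Against the 3 controls siCIP2A#1 and siCIP2A#2 both stood higher in the highest GC decile (0.10 and 0.22) than in the lowest (-0.02 and -0.11). Their excess of shared higher genes therefore cannot be told apart from a shared GC trend.

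With GC offsets edgeR called 509, 255 and 170 genes with the 3 siRNAs, and 0 higher genes and 1 lower gene, CIP2A, were common to all 3, where simulations gave 1.18 (0 to 4) and 1.22 (0 to 4). siCIP2A#1 and siCIP2A#2 shared 9 higher and 10 lower genes, against 1.83 and 3.01 for independent lists and 10.0 (4 to 17) and 12.5 (6 to 22) simulated. siCIP2A#1 and siCIP2A#3 shared 3 and 3, against 1.10 and 2.18 independent and 7.54 (3 to 12) and 10.4 (5 to 18) simulated. siCIP2A#2 and siCIP2A#3 shared 4 and 4, against 0.637 and 0.976 independent and 5.30 (1 to 12) and 5.40 (1 to 11) simulated. The simulated counts held neither a GC trend nor an effect of any siRNA, so noise filled their lists, much of it from the shared controls. Overlaps within or below these ranges do not argue against a shared effect.

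The spread between libraries was larger among siRNAs than among controls. The median SD of log2 CPM was 0.17 for the 3 siRNAs and 0.12 for the 3 controls, and the siRNA SD was larger for 64.2% of genes.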
